A study of Homo sapiens with 25 samples.

How the data were processed

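RNA was measured in 25 libraries of Jurkat cells, a human T-cell leukaemia line, kept at 100%, 50%, 25%, 12.5% or 0% histidine and sampled on day 3 or day 6. Per the labels' protocols, total RNA was extracted with QIAshredder and RNeasy Mini columns, and strand-specific Illumina libraries were made from 1 µg of it by a service provider. Per the submitters' processing notes, the tools were FastQC 0.11.9, kallisto 0.50.1, which estimates transcript abundance without base-level alignment, and DESeq2 1.44.0, with the build GRCh38. The role of each tool, the gene annotation and whether strand was used in counting are not given in the sources used here. The deposited values are a normalized signal, gene counts divided by a size factor per library, in 1 table of 36755 genes and 25 libraries, and every column was matched to its sample by name.

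The deposited signal was examined for whole reads. Between 51.7% and 75.4% of the low values of a library (up to 20 reads) came out as whole multiples of 1 read at a tolerance of 0.05, so whole reads were not recovered and no count model was run. The depth of each library is therefore not known. The totals lay between 18.44 and 21.38 mega-counts (median 19.86), are already normalized and do not give the depth. Whether the scaling used 1 size factor per library is not known from these values. No interval for counting error can be given. No pair of libraries held identical values.

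Gene names were used as the table gives them. Of the 36755 names, 36392 matched the gene name table, 10750 were Ensembl identifiers, and 23266 matched a gene of GENCODE 29, from which the printed coordinates (GRCh38, counted from 1) were taken. The authors' annotation may differ from it.

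Groups were taken from the sample labels: day and histidine level. For 9 groups and 25 libraries, log2(value + 1) was fitted with limma 3.58.1 in R 4.3.3 (statmod 1.5.0), with a mean per group, an intensity trend in the prior variance and robust moderation. All groups shared 1 estimate of the spread. Genes with a value of at least 10 in at least 2 libraries were tested, 22994 in all. P-values were adjusted by the Benjamini-Hochberg method within each comparison and a gene was called changed at an adjusted p under 0.05. The median of residual and prior degrees of freedom was 25.22. Fold changes are on the log2(value + 1) scale, which understates the change of genes with low values. The comparisons were each restricted level against 100% within a day, neighbouring levels within a day, day 6 against day 3 at 100%, and the difference between days of each effect of restriction.

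Gene lists were tested with camera at its preset correlation of 0.01, with a correlation estimated from the data, and with fry, all in limma. The 31 lists were ATF4 and CHOP stress targets, cytosolic aminoacyl-tRNA synthetases, amino acid transporters, serine, proline and one-carbon synthesis, histidine handling, cholesterol synthesis and uptake, G1/S and DNA replication, G2/M and mitosis, ribosome biogenesis, cytosolic ribosomal proteins, endoplasmic reticulum chaperones, cytosolic heat shock proteins, p53 targets, autophagy and lysosome, BCL2 family, glycolysis and hypoxia, nuclear-encoded respiratory chain, mitochondrially encoded mRNAs, T-lineage identity, T-cell activation and immediate early genes, NOTCH targets, interferon-stimulated genes, NRF2 and redox, purine and pyrimidine synthesis, host genes of small nucleolar RNAs and other transcripts sensitive to nonsense-mediated decay, replication-dependent histones, and B-cell, myeloid, epithelial, fibroblast and erythroid markers. Lists with at least 5 tested genes were tested as lists, 29 in all. The B-cell and erythroid markers, with 4 tested genes each, were not.

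The groups, the tests, the lists, the rule for named genes and the settings to be tried beside them were fixed before the data were examined. The rule took, in the widest comparison of each day (0% on day 3, 12.5% on day 6, each against 100%), the 6 largest rises and the 6 largest falls among changed genes whose libraries do not overlap, whose mean is at least 50 in 1 group and which have a symbol that is no clone, read-through or pseudogene name. It added the 4 changed members with the smallest p of each list that passed camera (2 of each other list), and in every comparison ASNS, DDIT3, TRIB3, CHAC1, SESN2, ATF3, HARS1, SLC7A11, MYC and CDKN1A. Other comparisons took 3 rises and 3 falls, and each difference between days the 4 largest. After the values had been seen, 45 members and leading genes from these 2 comparisons were followed through the others, among them HMGCS1, MKI67, TOP2A, CALR, MANF, DNAJB1, HSPA1B, HSPA8, SNHG12, GAS5, IMPDH2, GAPDH, RPL3, EGR1, CD3E, RAG1, RAG2, FTH1, TXNIP, SDK2 and CHGB. List members that went against the rest of their list, and the haemoglobin, matrix and heart transcripts, were also picked after their values had been seen.

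The settings fixed in advance were a pseudocount of 0.5 or 10, no filter on low values (36755 genes), a strict filter (mean of at least 50, 13090 genes), total-sum scaling, quantile normalization, only the compared groups in the fit, array weights, the replicate number as a block, leaving out each library in turn, and for lists the estimated correlation and fry. Tests on whole reads with edgeR and DESeq2 had been planned for the case that such reads were recovered and were not run. After the data had been seen, a term for the position of the library (its number in the labels modulo 8, 7 terms, leaving 9 residual degrees of freedom) and a fit without 3 day 6 libraries that stand apart were added.

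The procedure was tested on simulated data made from the real gene means and an assumed spread that was not estimated from these libraries. No position effect and no library that stands apart was simulated. In each comparison 100 genes were changed by 1.5-fold and 100 by 2-fold, all drawn from genes with a mean of at least 50. Recovery of changes in genes with lower means was therefore not measured. For day 3, 0% against 100% (21947 genes), 46% and 93% of them were recovered, and 7 of 146 calls were false. For day 3, 50% against 100% (21899 genes), the shares were 54% and 93%, with 5 false among 152 calls. For day 6, 25% against 100% (21946 genes), they were 62% and 95%, with 9 false among 166. For day 6, 12.5% against 100% (21957 genes), they were 44% and 93%, with 6 false among 143.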

Results

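The series asks how Jurkat cells, a human T-cell leukaemia line, respond in culture to a limited supply of histidine, an amino acid that human cells must take up from the medium. Gene expression was measured by RNA sequencing at different histidine levels and 2 time points. On day 3 there were 2 libraries at 100% histidine (replicates 1 and 3) and 3 each at 50%, 25%, 12.5% and 0%. On day 6 there were 3 libraries each at 100%, 50% and 25%, and 2 at 12.5%. The 25 libraries held between 17445 and 19624 genes with a normalized value of at least 10 (median 18156), and mitochondrial transcripts made up 2.23% to 5.4% of the values (median 3.91%). Nothing in the labels says that the replicates were separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

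Transcripts typical of other cell types varied between replicates. Haemoglobin alpha (HBA2) ranged from 41.19 to 2176 normalized counts over the 25 libraries, fibronectin (FN1) from 435.9 to 3774 and type I collagen (COL1A1) from 539.1 to 5519. The library of replicate 2 at 25% histidine on day 6 held 18210 normalized counts of MYH7, a heart muscle myosin, against at most 67.54 in any other library. The first 4 principal components took 14.65%, 8.697%, 7.34% and 5.551% of the variance. Replicate 3 of 100% and of 50% histidine on day 6 lay apart on the second component (-59.1 and -61.9). The library with MYH7 lay apart on components 3 and 4 (-84.6 and -94.6). The 2 libraries at 100% on day 3 also differed on the second component, with replicate 1 at 15.3 and replicate 3 at 57.1.

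**Figure D1:**
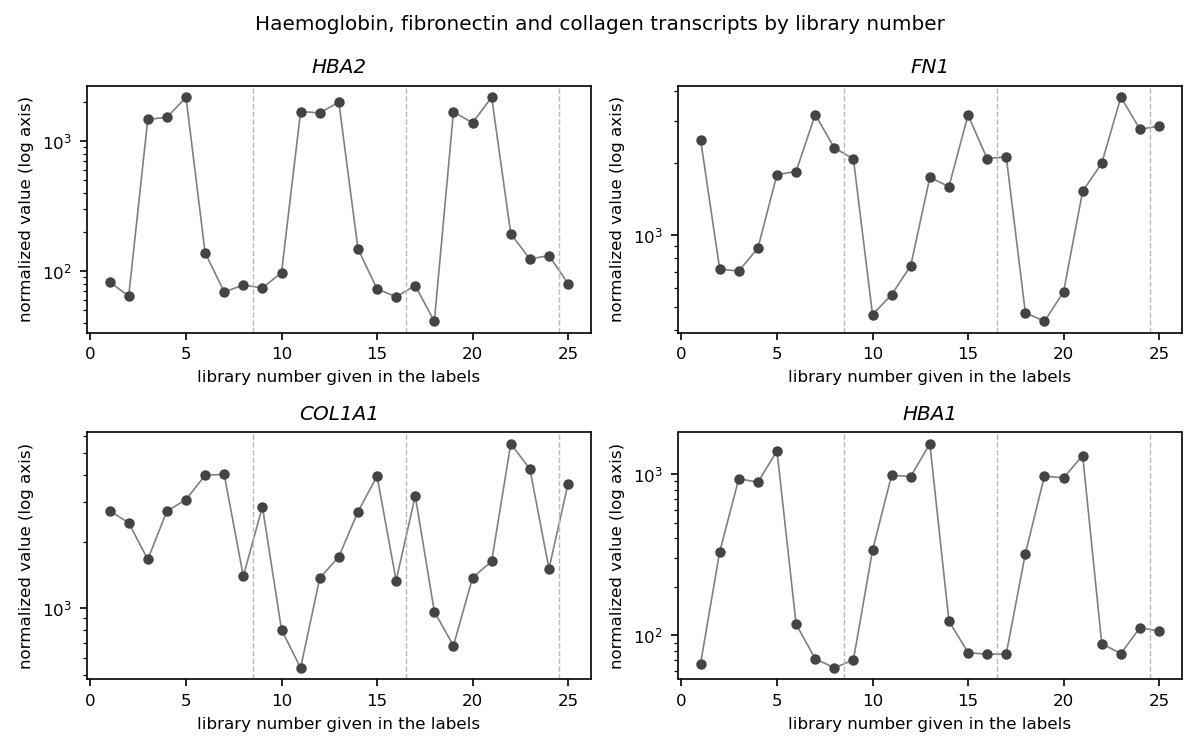
Normalized counts of HBA2, FN1, COL1A1 and HBA1 (log axis) in each of the 25 libraries against the library number of the labels, with dashed lines every 8 libraries. HBA2 ranges from 41.19 to 2176 and FN1 from 435.9 to 3774.

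**Figure D2:**
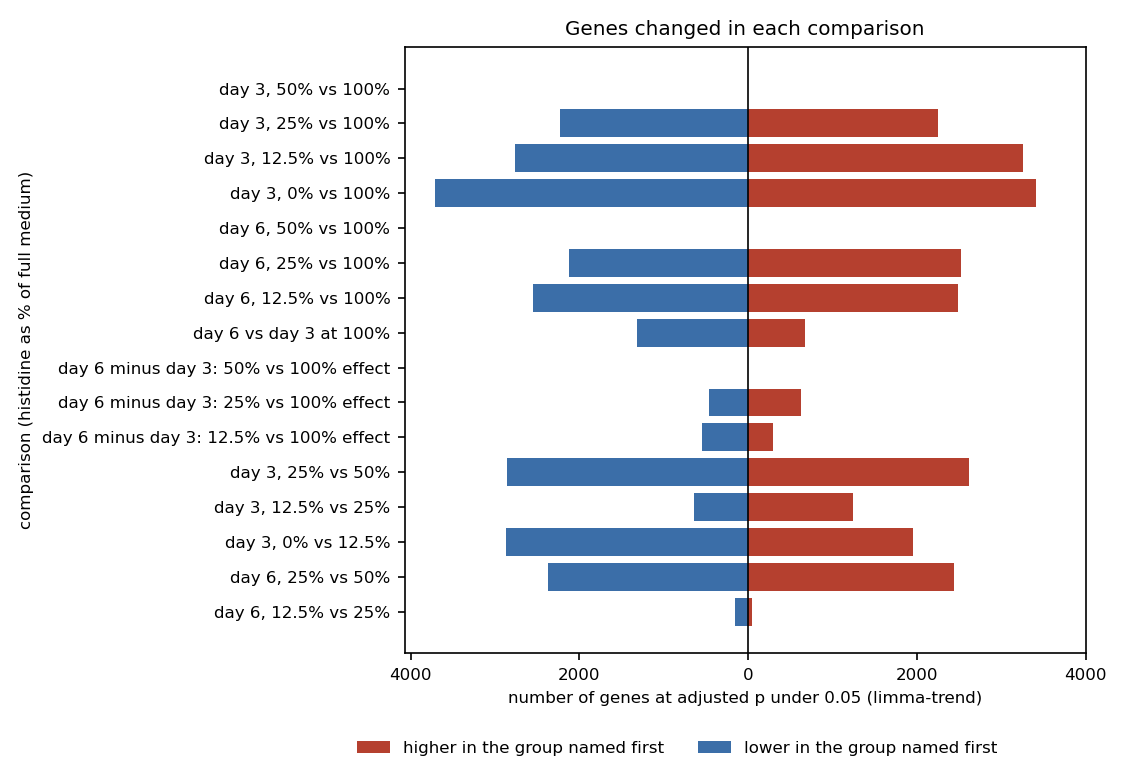
Bars give the number of genes higher (up) and lower (down) at an adjusted p under 0.05 in each of the 16 comparisons, out of 22994 tested. Restriction to 50% gave 0 genes on day 3 and 1 on day 6, while 25% gave 4490 and 4645.

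At 50% histidine on day 3 none of the genes followed here passed against 100%. HMGCS1, the HMG-CoA synthase of the cholesterol pathway, measured 11340 ± 176.9 normalized counts (SD, n = 3) against 10940 ± 587.8 (n = 2), a log2 difference of 0.05 (SE 0.078). TRIB3, a pseudokinase induced by ATF4, measured 4024 ± 155.5 against 4383 ± 317.6, and MYC 9848 ± 220.9 against 9679 ± 1181. No gene of 22994 passed limma's test, and 1075 had an unadjusted p under 0.05. Without replicate 1 of 100% the count was 5, as it was with only the compared groups in the fit. By camera 7 lists shifted at the preset correlation: cholesterol synthesis, G2/M and mitosis, ribosomal proteins, glycolysis, the nuclear-encoded respiratory chain and NRF2 targets upward and mitochondrial mRNAs downward, with 0 members of each passing over all genes and 0 adjusted over the list alone. The count of lists was 1 without replicate 1 of 100%, 12 without replicate 3 and 4 under quantile normalization. None held with an estimated correlation, where the smallest adjusted p was 0.576. HBA2 measured 1722 ± 390.7 at 50% and 73.64 ± 12.99 at 100%. Over all groups it averaged 1612, 1519 and 2113 at the positions (number modulo 8) of these libraries at 50%. At the positions of those at 100% it averaged 78.79 and 67.78, so position and histidine cannot be told apart for HBA2 here.

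At 25% histidine on day 3 sterol and heat shock transcripts were lower and a set of small nucleolar RNA host genes was higher than at 100%. HMGCS1 (ENSG00000112972.14, chromosome 5, 43289395 to 43313512) was 8.67-fold lower, at 1261 ± 32.92 (n = 3) against 10940 ± 587.8 (n = 2; log2 -3.12, SE 0.078, adjusted p = 6.12e-20). TXNIP, an arrestin-fold inhibitor of glucose uptake (ENSG00000265972.5, chromosome 1, 145992435 to 145996600), was 10.9-fold higher, at 8954 ± 214.7 against 823.3 ± 113.1 (log2 3.45, SE 0.095, adjusted p = 3.01e-19). TRIB3 (ENSG00000101255.10, chromosome 20, 362835 to 397559) was 4.78-fold higher (log2 2.26, SE 0.087), and MYC (ENSG00000136997.17, chromosome 8, 127735434 to 127741434) was 3.23-fold lower (log2 -1.69, SE 0.081).

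Among the 24 genes of cholesterol synthesis and uptake, 22 fell and 1 rose at 25% on day 3 (22 and 1 adjusted over the list alone, median log2 -1.64; adjusted p = 1.19e-39, and 0.000111 with an estimated correlation). They included INSIG1 (log2 -2.33). Of 15 cytosolic heat shock proteins 14 fell and 1 rose (14 and 1 adjusted over the list alone, median -1.17; adjusted p = 0.000369 with an estimated correlation). DNAJB1, a partner of HSP70, went from 24180 ± 368.9 to 2466 ± 130.1, and HSPA8, the constitutive HSP70, changed by -1.99. Of 26 glycolysis and hypoxia genes 20 fell (20 adjusted over the list alone, 0.0105 with an estimated correlation), with ALDOC at -1.86 and GAPDH at -0.58. Purine and pyrimidine synthesis had 9 of 19 lower (10 adjusted over the list alone, 0.0197 with an estimated correlation), with IMPDH2, the rate-limiting enzyme of guanine nucleotide synthesis, at -1.21 (SE 0.063). Of 17 host genes sensitive to nonsense-mediated decay, 9 rose and 1 fell (9 and 1 adjusted over the list alone, 0.0197 with an estimated correlation). SNHG12 rose from 72.79 ± 18.1 to 983.2 ± 42.09, and GAS5 by 1.27 (SE 0.096).

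Other lists at 25% on day 3 passed only at the preset correlation. ATF4 and CHOP targets had 9 of 24 higher and 3 lower (10 and 3 adjusted over the list alone, adjusted p = 0.00481, and 0.0639 with an estimated correlation). CEBPG, a partner of ATF4, rose by 1.23, while DDIT4, an inhibitor of mTORC1, changed by -0.97. ASNS, asparagine synthetase, did not pass (log2 0.1, SE 0.093, adjusted p = 0.548), nor did DDIT3, which encodes CHOP (0.33, SE 0.123, adjusted p = 0.0651). Ribosome biogenesis had 16 of 24 lower and 1 higher (17 and 2 adjusted over the list alone, adjusted p = 0.0746 with an estimated correlation). T-lineage identity had 13 of 32 lower and 3 higher (14 and 6 adjusted over the list alone, 0.106 with an estimated correlation), T-cell activation 11 of 25 lower (13 adjusted over the list alone, 0.106), and NRF2 targets 6 of 18 lower and 3 higher (7 and 3 adjusted over the list alone, 0.212). Ribosomal proteins had 29 of 59 lower and 1 higher (29 and 2 adjusted over the list alone, adjusted p = 0.481 with an estimated correlation), with a median of -0.15 as deposited, -0.07 under total-sum scaling and 0 under quantile normalization. Mitochondrial mRNAs had 0 of 13 (0 adjusted over the list alone, adjusted p = 0.654 with an estimated correlation).

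In total 4490 genes differed between 25% and 100% on day 3, 2256 higher (50.24%) and 2234 lower. Total-sum scaling gave 63.31% higher. With library position in the fit 2350 genes passed, and without replicate 3 of 100% histidine 2954 did. The largest rises by the naming rule rested on few normalized counts at 100%: SCN3B (log2 4.98, adjusted p = 0.00805) reached 2.71 at an adjusted p of 0.235 without that library. DISP1 (4.79, adjusted p = 0.0351) did not pass with position in the fit (3.42, adjusted p = 0.471), nor without replicate 1 (0.0554) or 3 (0.28) of 100% or replicate 2 (0.0985) or 3 (0.0938) of 25%. RIGI (4.46, SE 0.865) measured 20.1 and 0 in the 2 libraries at 100%. The largest falls were HSPA6 (-6.68, SE 0.646), HSPA1B (-6.31, SE 0.352) and MYL4 (-4.59, SE 0.87), the last -3.42 at an adjusted p of 0.0755 with position in the fit. HSPA1B and HSPA1A are near-identical copies, so how reads were divided between them is uncertain.

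At 12.5% histidine on day 3 sterol and heat shock transcripts stayed below the 100% level. MKI67, the proliferation antigen Ki-67 (ENSG00000148773.13, chromosome 10, 128096659 to 128126385), measured 17050 ± 1123 (n = 3) against 12200 ± 801.3 (n = 2; log2 0.48, SE 0.088, adjusted p = 0.000163), and PLK1, a mitotic kinase, was higher by 0.94 (SE 0.081). HMGCS1 was 9.24-fold lower (log2 -3.21) and MYC 4.63-fold lower (-2.21, SE 0.081). TRIB3 was 6.08-fold higher (2.6, SE 0.087), TXNIP 14.1-fold higher (3.82, SE 0.095), SESN2 was higher by 0.72 and DDIT3 by 0.72. RAG2, which with RAG1 rearranges T-cell receptor genes, was 5.05-fold lower, at 202 ± 33.4 against 1014 ± 19.9.

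Of the 24 cholesterol genes 22 fell and 1 rose at 12.5% (22 and 1 adjusted over the list alone, adjusted p = 0.000302 with an estimated correlation). Heat shock proteins had 13 of 15 lower and 1 higher (14 and 1 adjusted over the list alone, 0.00445). ATF4 and CHOP targets had 13 of 24 higher and 3 lower (13 and 4 adjusted over the list alone, 0.0355), autophagy and lysosome genes 10 of 27 higher and 1 lower (10 and 1, 0.0355), and glycolysis and hypoxia 21 of 26 lower and 2 higher (22 and 2, 0.0355). T-lineage identity had 15 of 32 lower and 5 higher (16 and 5, 0.0394), purine synthesis 8 of 19 lower and 1 higher (9 and 1, 0.0448), and the decay-sensitive host genes 9 of 17 higher and 1 lower (9 and 2, 0.0496). CD3E, a chain of the T-cell receptor complex, went against its list and rose by 0.59 (SE 0.045). G2/M and mitosis had 18 of 25 higher and 3 lower (18 and 3 adjusted over the list alone, adjusted p = 1.19e-07, and 0.072 with an estimated correlation), the 3 being AURKB, BUB1B and TTK.

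The calls of G1/S and DNA replication (12 of 29 higher, 3 lower; 16 and 3 adjusted over the list alone) were lost at an adjusted p of 0.246 with an estimated correlation at 12.5%. So were those of NOTCH targets (3 of 13 lower, 0.151), T-cell activation (10 of 25 lower, 1 higher, 0.229), ribosome biogenesis (11 of 24 lower, 2 higher, 0.186), ribosomal proteins (24 of 59 lower, 9 higher, 0.821) and mitochondrial mRNAs (1 of 13 lower, 0.672). In total 6018 genes differed, 3257 higher and 2761 lower. The largest rises by the naming rule were SCN3B (5.2), DISP1 (5.17) and PRSS16 (5.15). Without replicate 3 of 100% SCN3B was at 2.93 (adjusted p = 0.145) and DISP1 at 4.08 (0.175), and without replicate 1 of 100% PRSS16 was at 4.39 (0.157). With position in the fit DISP1 did not pass (0.0611), and without replicate 2 of 12.5% DISP1 (0.0611) and PRSS16 (0.0571) did not pass. The largest falls were HSPA6 (-7.16), HSPA1B (-6.31) and MYL4 (-5.47).

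Without histidine on day 3 the cell cycle transcripts fell below the 100% level. TOP2A, the topoisomerase of dividing cells, measured 2941 ± 160.8 (n = 3) against 10020 ± 220.2 (n = 2; log2 -1.77, SE 0.06, adjusted p = 1.21e-17), and MKI67 4237 ± 258.9 against 12200 ± 801.3 (-1.53, SE 0.088). All 25 genes of G2/M and mitosis fell (25 adjusted over the list alone, median -1.55), and 28 of 29 genes of G1/S and DNA replication (28 adjusted over the list alone, median -1.18), both at an adjusted p of 0.000438 with an estimated correlation. The G1/S members included RRM1 (-1.65), MCM10 (-1.94) and TYMS (-1.71). TERT, the catalytic subunit of telomerase (ENSG00000164362.19, chromosome 5, 1253147 to 1295069), went from 257.9 ± 63.4 to 2.052 ± 2.701 (log2 -6.78, SE 1.104, adjusted p = 9.32e-05).

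Sterol transcripts stayed low without histidine on day 3, with 22 of 24 lower and 1 higher (22 and 1 adjusted over the list alone, median -1.76; adjusted p = 0.000438 with an estimated correlation). HMGCS1 was 9.13-fold lower (1197 ± 18.31; log2 -3.19, SE 0.078, adjusted p = 8.46e-21). PMVK, phosphomevalonate kinase, was the 1 member that rose. Glycolysis and hypoxia had 21 of 26 lower and 1 higher (22 and 1 adjusted over the list alone, 0.0293 with an estimated correlation), with ALDOC at -1.99, PFKL at -1, TPI1 at -0.8 and GAPDH at -0.77. Purine and pyrimidine synthesis had 12 of 19 lower and 2 higher (12 and 2 adjusted over the list alone, 0.0439), with GMPS at -1.25 and IMPDH2 at -1.1. Autophagy and lysosome genes had 14 of 27 higher and 2 lower (14 and 4 adjusted over the list alone, 0.0171), with GABARAPL1 at 0.94, CTSD at 0.87, BECN1 at 0.75 and ULK1 at 0.73. The decay-sensitive host genes had 9 of 17 higher and 2 lower (9 and 2 adjusted over the list alone, 0.0439), with SNHG5 at 2.84, SNHG12 at 2.45, SNHG32 at 1.91 and GAS5 at 1.42.

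TRIB3 reached 28040 ± 465.1 without histidine, 6.41-fold above 100% (log2 2.68, SE 0.087, adjusted p = 5.23e-17). Of the 24 ATF4 and CHOP targets 11 rose and 4 fell (11 and 5 adjusted over the list alone, adjusted p = 0.00941, and 0.0716 with an estimated correlation). ATF5 rose by 1.12, CEBPG by 1.03, SLC7A11, the cystine transporter, by 0.8 and DDIT3 by 0.73. ASNS did not pass (-0.09, SE 0.093, adjusted p = 0.515) and ATF3 fell by 1.09. Aminoacyl-tRNA synthetases had 10 of 20 higher and 6 lower (12 and 6 adjusted over the list alone, adjusted p = 0.0494, 0.083 with position in the fit and 0.622 with an estimated correlation). MARS1 and WARS1 rose by 0.67 each and SARS1 by 0.65, while QARS1, the glutaminyl-tRNA synthetase, changed by -1.11. HARS1, the histidyl-tRNA synthetase, was higher by 0.26 (SE 0.075, adjusted p = 0.00901), but not with position in the fit (adjusted p = 0.0797) or without replicate 1 of 100% (0.2, adjusted p = 0.135) or replicate 1 of 0% (0.21, 0.0521).

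Heat shock proteins had 10 of 15 lower and 3 higher without histidine (10 and 3 adjusted over the list alone, adjusted p = 0.00028, and 0.122 with an estimated correlation). HSPA6, an inducible HSP70, went from 5423 ± 115.1 to 32 ± 20.44 and HSPA1B from 19940 ± 1811 to 194.8 ± 37.7, whereas HSPA8, HSPA4 and DNAJA1 rose, HSPA8 by 0.56. T-cell activation genes had 11 of 25 lower and 1 higher (11 and 1 adjusted over the list alone, 0.298), with EGR1 at -2.43 and DUSP2 at -1.64. NOTCH targets had 6 of 13 lower (6 adjusted over the list alone, adjusted p = 0.00218, and 0.0601 with an estimated correlation), with DTX1 at -1.25 and NOTCH1 at -0.99. Ribosomal proteins had 25 of 59 higher and 4 lower (26 and 5 adjusted over the list alone, adjusted p = 0.697 with an estimated correlation), but 13 higher and 11 lower under quantile normalization (median 0.18 to 0.07).

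The other lists did not pass camera at 0% against 100%. T-lineage identity had 10 of 32 higher and 11 lower (10 and 11 adjusted over the list alone), with CD3E at 0.89 and the kinase FYN at 1.22. Amino acid transporters had 9 of 21 higher and 2 lower (10 and 4), with SLC7A5 at 0.5 and SLC38A5, a carrier of histidine and glutamine, at -1.47. Serine, proline and one-carbon synthesis had 3 of 15 higher and 6 lower (3 and 6), with CBS at -0.71. Histidine handling had 3 of 11 higher and 0 lower (4 and 0), among them CNDP2, which cleaves carnosine-like dipeptides, at 0.88. Endoplasmic reticulum chaperones had 9 of 19 higher and 3 lower (10 and 5), ribosome biogenesis 5 of 24 higher and 2 lower (5 and 2), and p53 targets 6 of 20 higher and 3 lower (6 and 5), with the test upward and the median at -0.05. The BCL2 family had 4 of 16 higher and 4 lower (5 and 4), the respiratory chain 4 of 33 higher and 7 lower (4 and 7), and mitochondrial mRNAs 0 of 13 (0). Interferon-stimulated genes had 5 of 31 higher and 6 lower (5 and 6), with IRF7 4.22-fold higher (2.08, SE 0.198). NRF2 targets had 10 of 18 higher and 4 lower (10 and 5), with the ferritin chain FTH1 at 0.93 and TKT at -0.93, and replication-dependent histones 2 of 18 higher and 2 lower (2 and 2).

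Among markers of other cell types at 0% against 100%, 0 of 9 myeloid, 1 of 7 epithelial (KRT18, -0.93) and 1 of 8 fibroblast markers (THY1, -1.32) fell and 0 rose, with the same counts adjusted over each list alone. Of the 4 B-cell markers tested, CD79A rose by 1.5. HBA2, of the erythroid list, measured 1263 ± 979.9 at 0% and 73.64 ± 12.99 at 100%, and COL1A1 1932 ± 702.8 and 2590 ± 228.7. HBA2 followed the library number in steps of 8, as described below. Other large changes without histidine were CHGB, the secretory granule protein chromogranin B (26.5-fold higher; 649 ± 70.86 against 26.13 ± 16.72), CNTN4 (20.5-fold higher), LINC00237 (log2 4.57), IFITM5 (4.08), TTLL7 (-5.91) and SDK2 (-5.9). LINC01670 (-4.94) did not pass with position in the fit (-5.09, adjusted p = 0.128) or without replicate 1 of 100% (-4.7, 0.0511). SCN3B was at 5.44, and at 3.17 with an adjusted p of 0.101 without replicate 3 of 100%. In total 7123 genes differed, 3411 higher and 3712 lower, and 765 and 1643 of them by at least 2-fold. With position in the fit the count was 4725.

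**Figure D3:**
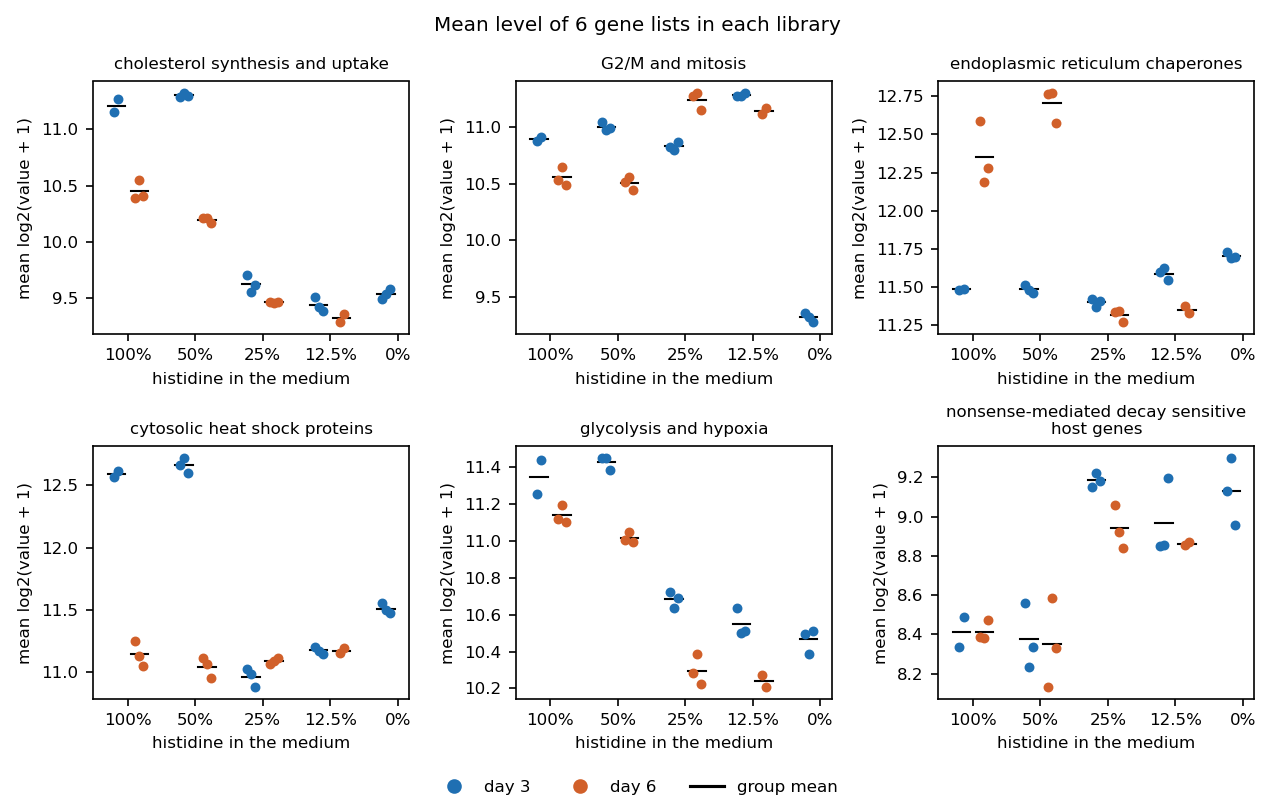
Each panel gives the mean log2(value + 1) over the members of 1 gene list in each library (points) against the histidine level, with day 3 in blue, day 6 in orange and group means as black lines. On day 3 the G2/M list lies above the 100% level at 12.5% and below it at 0%, and the cholesterol list is low at 25% and below on both days.

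Between neighbouring levels on day 3 the step from 50% to 25% changed the most genes. TXNIP rose 10.3-fold (log2 3.36, SE 0.085), SNHG12 16.6-fold (4.06, SE 0.156) and CNTN4 22.6-fold (4.5, SE 0.491), and HMGCS1 fell from 11340 ± 176.9 to 1261 ± 32.92 (n = 3 each; -3.17, SE 0.07, adjusted p = 2.51e-21). HSPA1B fell from 23930 ± 4208 to 267.1 ± 123.7 (-6.56, SE 0.314). Cholesterol genes (22 of 24 lower, 1 higher, adjusted p = 0.000138 with an estimated correlation), heat shock proteins (14 of 15 lower, 1 higher, 0.000508), glycolysis (21 of 26 lower, 0.00566), purine synthesis (11 of 19 lower, 0.0111) and the decay-sensitive host genes (9 of 17 higher, 1 lower, 0.0392) passed with both correlations. In total 5475 genes differed, 2612 higher (47.71%) and 2863 lower, and 3183 with position in the fit. Total-sum scaling, which moved the median of all genes from 0.014 to 0.113, gave 63.99% higher. The 9 other lists that passed at the preset correlation had adjusted p of at least 0.0702 with an estimated one. Among them was the respiratory chain, whose median of -0.08 became 0.02 under total-sum scaling.

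From 25% to 12.5% on day 3 mitotic transcripts rose, with 19 of 25 higher (21 adjusted over the list alone, median 0.47; adjusted p = 0.00441 with an estimated correlation), PLK1 by 0.66 (SE 0.072) and TOP2A by 0.36 (SE 0.054). Autophagy and lysosome genes had 8 of 27 higher (11 and 1 lower adjusted over the list alone, 0.0181), and 3 higher under total-sum scaling. HSPA8 rose from 4524 ± 384.1 to 9927 ± 1279, FTH1 by 0.56, and MYC (-0.52), RAG1 (-0.88) and RAG2 (-1.07) were lower. HMGCS1 did not pass (-0.09, SE 0.07, adjusted p = 0.513). Of 1889 genes 65.8% were higher, against 35.35% under total-sum scaling and 50% of 1232 genes under quantile normalization. With position in the fit 238 genes passed, and 1135 or 1215 without replicate 2 or 3 of 25%. The 11 other lists that passed at the preset correlation had adjusted p of at least 0.0505 with an estimated one.

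From 12.5% to 0% on day 3 the cell cycle lists fell, G2/M in 25 of 25 (25 adjusted over the list alone, median -1.97) and G1/S in 28 of 29 (29 adjusted over the list alone, median -1.38), both at an adjusted p of 1.73e-05 with an estimated correlation. MKI67 fell 4.02-fold (-2.01, SE 0.079) and PLK1 by 2.28. T-lineage identity rose in 21 of 32 and fell in 2 (22 and 2 adjusted over the list alone, 0.000968), with RAG1 at 0.89, RAG2 at 0.81 and CD3E at 0.3, and ribosome biogenesis rose in 14 of 24 and fell in 1 (18 and 1 adjusted over the list alone, 0.0452). MYC rose by 0.68 (SE 0.072), HSPA8 by 1.42 and RPL3 by 0.8, and SNHG12 fell from 972.8 ± 70.07 to 398.7 ± 49.19. Ribosomal proteins had 39 of 59 higher (48 adjusted over the list alone, adjusted p = 1.99e-20, and 0.286 with an estimated correlation). TRIB3 (0.08) and HMGCS1 (0.02) did not pass. In total 4818 genes differed, 1954 higher and 2864 lower, and 2723 with position in the fit.

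**Figure D4:**
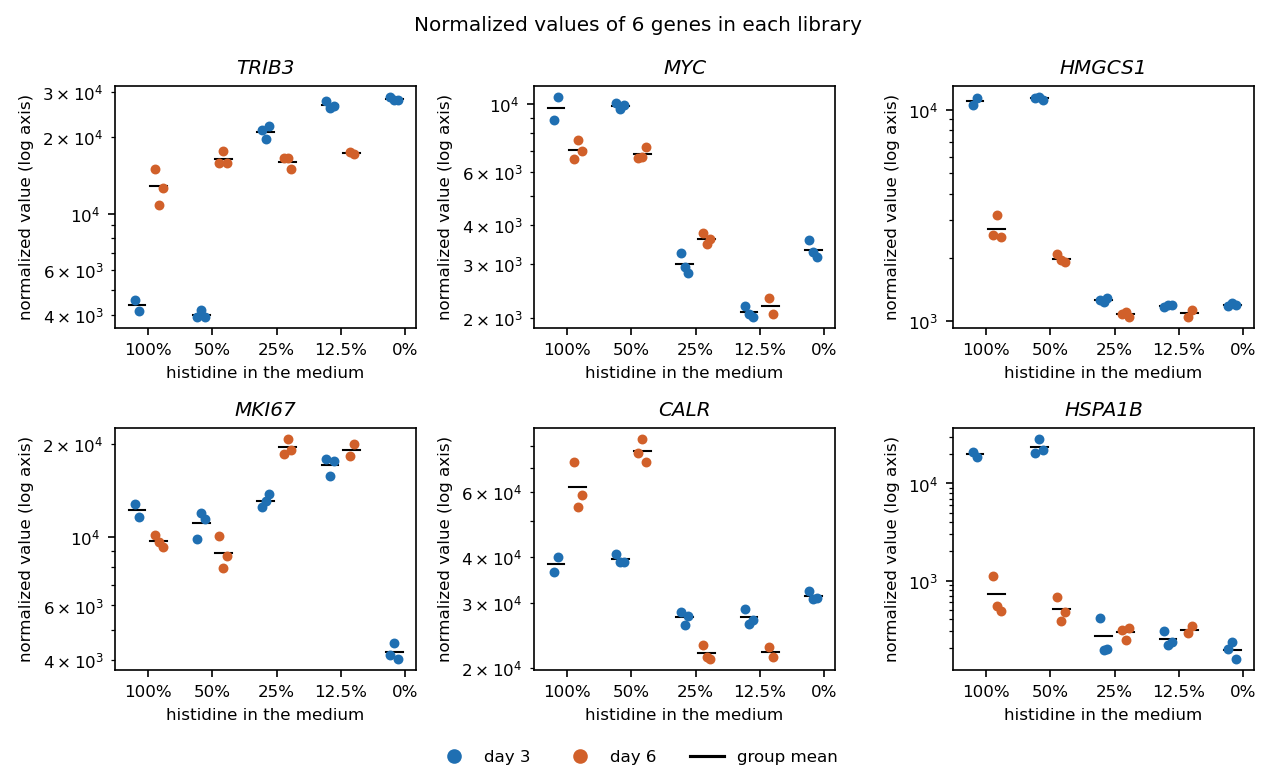
Normalized counts of TRIB3, MYC, HMGCS1, MKI67, CALR and HSPA1B in each library (points, log axis) against the histidine level, with day 3 in blue, day 6 in orange and group means as black lines. HSPA1B is at 19940 and 23930 in the day 3 groups with 100% and 50% histidine and at 720.8 or less in every other group.

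On day 6 restriction to 50% changed HMGCS1 alone among 22994 genes by limma, with 1098 genes at an unadjusted p under 0.05. HMGCS1 measured 1976 ± 87.52 against 2741 ± 381.7 (n = 3 each; log2 -0.46, SE 0.07, adjusted p = 0.0129). It did not pass with position in the fit (-0.49, adjusted p = 1) or without replicate 2 of 100% (adjusted p = 0.0601), replicate 2 of 50% (0.084) or replicate 3 of 50% (0.0596). Without replicate 1 of 100%, 17 genes passed, with array weights 5 and with only the compared groups in the fit 4. The cholesterol list shifted downward (1 of 24 lower over all genes and 13 adjusted over the list alone, median -0.23; adjusted p = 0.00528 with an estimated correlation). Endoplasmic reticulum chaperones shifted upward (0 of 19 over all genes and 15 adjusted over the list alone, median 0.33; 0.00566), with MANF at 7080 ± 508.3 against 4964 ± 856.5. Myeloid markers also shifted upward (0 of 9 over all genes and 2 adjusted over the list alone, 0.013, and 0.158 at the preset correlation with the position term in the fit). Fibroblast markers (median -0.82; 0.187) and epithelial markers (median -0.64; 0.187) passed only at the preset correlation. So did G2/M, ribosomal proteins, heat shock, glycolysis, mitochondrial mRNAs and T-cell activation, at adjusted p of at least 0.213 with an estimated one. COL1A1 measured 1006 ± 349.3 at 50% and 2830 ± 1347 at 100%, FN1 496.5 ± 74.05 and 2463 ± 617.5, and HBA2 1034 ± 871.9 and 71.47 ± 7.163. The libraries at 50% are numbers 18 to 20 in the labels and those at 100% numbers 15 to 17. Over all groups FN1 averaged 553.7, 569 and 735.8 at the positions (number modulo 8) of the former, and 3381, 2393 and 2394 at those of the latter. Position and histidine therefore cannot be told apart for these transcripts here.

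At 25% histidine on day 6 mitotic transcripts were higher and endoplasmic reticulum chaperones lower than at 100%. MKI67 measured 19440 ± 1118 against 9677 ± 407.7 (n = 3 each; 2.01-fold; log2 1.01, SE 0.079, adjusted p = 1.05e-09). CALR, the calcium-binding chaperone calreticulin (ENSG00000179218.13, chromosome 19, 12938578 to 12944489), measured 21940 ± 1080 against 61940 ± 9200 (-1.49, SE 0.073, adjusted p = 9.29e-13). TXNIP was 24.6-fold higher, at 12790 ± 131.7 against 518.5 ± 21.14 (4.62, SE 0.085, adjusted p = 2.51e-23), and SNHG12 (ENSG00000197989.14, chromosome 1, 28578538 to 28583132) 11.4-fold (3.5, SE 0.156). SDK2, a cell adhesion protein, was 34.6-fold lower (-5.11, SE 0.712) and the chemokine receptor CCR8 7.34-fold lower (-2.88, SE 0.327). TRIM63, named among the largest rises, was at 353.7 in the library with MYH7 and at 5.3 and 10.2 in the others of its group, and did not pass without it (1.8, adjusted p = 0.201).

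Of the 25 G2/M genes 23 rose at 25% on day 6 (23 and 1 lower adjusted over the list alone, median 0.76; adjusted p = 0.00254 with an estimated correlation), with PLK1 at 1.28 and TPX2 at 0.94. Cholesterol genes had 20 of 24 lower and 1 higher (22 and 1 adjusted over the list alone, 0.00072), with HMGCS1 2.52-fold lower (-1.33, SE 0.07). Endoplasmic reticulum chaperones had 17 of 19 lower (17 adjusted over the list alone, median -0.86; 0.00693), glycolysis and hypoxia 21 of 26 lower and 1 higher (23 and 1, 0.004), and purine synthesis 12 of 19 lower (13, 0.00418). Autophagy and lysosome genes had 8 of 27 higher (8, 0.0378), and the decay-sensitive host genes 9 of 17 higher (9, 0.0325). Ribosomal proteins had 38 of 59 lower (43 adjusted over the list alone), with adjusted p = 7.95e-22, and 0.188 with an estimated correlation. The calls of tRNA synthetases (4 of 20 higher, 9 lower, adjusted p = 0.34 with an estimated correlation), amino acid transporters (2 of 21 higher, 7 lower, 0.102), serine and one-carbon synthesis (3 of 15 higher, 8 lower, 0.17), ribosome biogenesis (2 of 24 higher, 7 lower, 0.34) and T-lineage identity (7 of 32 higher, 14 lower, 0.0806) were lost.

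ATF4 and CHOP targets did not pass at 25% on day 6 (5 of 24 higher and 6 lower, adjusted p = 0.564). ASNS was lower by log2 -0.61 (SE 0.084) and DDIT3 by -0.74 (SE 0.11), while SLC7A11 was higher by 0.43. Heat shock proteins did not pass either (5 of 15 higher, 4 lower), with DNAJB1 at -0.19 (SE 0.083, adjusted p = 0.111). In total 4645 genes differed, 2521 higher and 2124 lower, and 3012 with position in the fit.

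At 12.5% histidine on day 6 mitotic transcripts were again above the 100% level, with 20 of 25 G2/M genes higher and 1, AURKB, lower (20 and 1 adjusted over the list alone, adjusted p = 0.00613 with an estimated correlation). Cholesterol genes had 21 of 24 lower (22 and 1 higher adjusted over the list alone, 0.000875), with DHCR7 at -1.9, INSIG1 at -1.89 and HMGCS1 at -1.32. Endoplasmic reticulum chaperones had 17 of 19 lower (17 adjusted over the list alone, 0.0149), with SDF2L1 at -2.32, MANF at -1.91 and CALR at -1.48. Glycolysis and hypoxia had 23 of 26 lower (23, 0.00564), purine synthesis 12 of 19 lower (15, 0.00564), autophagy and lysosome 11 of 27 higher (14, 0.00564) and the decay-sensitive host genes 8 of 17 higher (9, 0.0492). IMPDH2 (ENSG00000178035.11, chromosome 3, 49024325 to 49029408) measured 1700 ± 51.04 (n = 2) against 5615 ± 170.9 (n = 3; -1.72, SE 0.063, adjusted p = 1.08e-16). TXNIP was 18.3-fold higher and MYC 3.23-fold lower (2189 ± 181.8 against 7069 ± 506).

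Lists lost with an estimated correlation at 12.5% on day 6 were T-cell activation (14 of 25 higher, 1 lower; 17 and 2 adjusted over the list alone, adjusted p = 0.294), with EGR3 at 2.76, IRF4 at 2.17 and JUND at 0.64, and NRF2 targets (7 of 18 higher, 2 lower; 8 and 2; 0.162), with NQO1 at 1.02, FTH1 at 0.89 and TKT at -0.94. NOTCH targets had 5 of 13 lower (7 and 1 higher adjusted over the list alone, adjusted p = 0.0716 with an estimated correlation), with PTCRA, the pre-T-cell receptor alpha chain, at -2.29. T-lineage identity had 14 of 32 lower and 6 higher (14 and 8, 0.0989), with RAG2 at -2.3, RAG1 at -1.6, CD1B at -1.49 and CD3E at 0.46. The calls of ribosome biogenesis (12 of 24 lower, 4 higher, 0.162), ribosomal proteins (37 of 59 lower, 2 higher, 0.252), tRNA synthetases (10 of 20 lower, 4 higher, 0.413) and serine and one-carbon synthesis (7 of 15 lower, 1 higher, 0.162) were also lost.

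QARS1 was 3.11-fold lower, CBS changed by -1.08 and RPL3 by -1.02 at 12.5% on day 6. ATF4 and CHOP targets did not pass (7 of 24 higher, 5 lower, adjusted p = 0.99), with DDIT3 2.41-fold lower (-1.27, SE 0.123) and TRIB3 1.37-fold higher (0.45, SE 0.087; adjusted p = 0.101 with only the compared groups in the fit). Among the 6 largest rises, EGR2 (3.14) did not pass without replicate 1 of 12.5% (adjusted p = 0.0696) and had a position effect (range of log2 2.65, adjusted p = 0.0403), CCL4 (4.51) without either library of 12.5% (0.134 and 0.116) or without replicate 1 (0.0511) or 3 (0.122) of 100%, and IL2RA (3.4) without any of the 5 libraries compared (adjusted p of 0.0624 to 0.18). CCR8 (-3.68, SE 0.366), PRDM16-DT (-3.83) and LDLRAD2 (-3.48) were among the largest falls, as was CFTR (-4.38; adjusted p = 0.163 without replicate 1 of 12.5%) and MIR223HG (-3.31, adjusted p = 0.0482; 0.0513 with position in the fit, and 0.0537 to 0.306 without any of the 5 libraries). In total 5036 genes differed, 2482 higher and 2554 lower, and 3175 without replicate 2 of 12.5%.

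Between neighbouring levels on day 6 the step from 50% to 25% changed 4807 genes, 2436 higher and 2371 lower (2432 genes with position in the fit). CALR fell from 77670 ± 5563 to 21940 ± 1080 and MANF 4.8-fold (-2.26, SE 0.099), with 18 of 19 endoplasmic reticulum chaperones lower (adjusted p = 0.00325 with an estimated correlation). TXNIP rose 28.2-fold (4.82, SE 0.085). Cholesterol genes had 20 of 24 lower and 1 higher (0.00188), G2/M 23 of 25 higher (0.00188), purine synthesis 12 of 19 lower (0.00545), glycolysis 22 of 26 lower and 1 higher (0.00693) and the decay-sensitive host genes 8 of 17 higher (0.0453). The 6 other lists that passed at the preset correlation had adjusted p of at least 0.0538 with an estimated one. From 25% to 12.5% on day 6, 201 genes differed, 47 higher and 154 lower. DNTT, which adds nucleotides to antigen receptor junctions (ENSG00000107447.7, chromosome 10, 96304396 to 96338564), was lower (-1.56, SE 0.056, adjusted p = 3.67e-16), as were RAG1 (-1.19) and MYC (-0.73), and ARRDC3 was higher (1.63, SE 0.103). By camera NRF2 targets shifted upward (5 of 18 higher; 8 adjusted over the list alone, 0.0268), as did autophagy (1 of 27 higher; 4; 0.0453), and NOTCH targets shifted downward (3 of 13 lower; 4 and 1 higher; 0.0453). The 6 other lists had adjusted p of at least 0.224. With position in the fit 32 genes passed, with only the compared groups in the fit 12 and with array weights 328. The count was 100 without the 3 day 6 libraries that stand apart, 74 or 82 without replicate 2 or 1 of 12.5%, and 113 or 322 without replicate 2 or 3 of 25%.

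Day 6 was compared with day 3 at 100% histidine to see how unrestricted cells differed. Heat shock proteins were lower in 13 of 15 (14 adjusted over the list alone, median -1.16; adjusted p = 3.96e-05 with an estimated correlation), with HSPA1B at 720.8 ± 350.4 (n = 3) against 19940 ± 1811 (n = 2; -4.89, SE 0.352) and DNAJB1 9.39-fold lower. Cholesterol genes were lower in 18 of 24 (20 and 1 higher adjusted over the list alone, 0.000149), with HMGCS1 4.01-fold lower (-2, SE 0.078). Endoplasmic reticulum chaperones were higher in 17 of 19 (18 and 1 lower, 0.00259), with MANF 2.7-fold higher (1.43, SE 0.11) and CALR by 0.69. DDIT3 (ENSG00000175197.12, chromosome 12, 57516588 to 57521737) was 3.53-fold higher (1161 ± 171.8 against 326.3 ± 6.475), TRIB3 2.89-fold higher and KLHDC7B was at 178.7 ± 45.1 against 22.59. EGR1 was lower (-2.08, SE 0.182).

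ATF4 and CHOP targets were higher in 8 of 24 and lower in 4 at 100% on day 6 against day 3 (10 and 4 adjusted over the list alone, adjusted p = 0.0179 with an estimated correlation). G1/S was lower in 20 of 29 (22, 0.00259), G2/M in 20 of 25 (20, 0.00653), ribosome biogenesis in 11 of 24 (18, 0.00653), NRF2 targets in 10 of 18, with 1 higher (11 and 1, 0.00653), purine synthesis in 8 of 19 (12, 0.00653) and T-cell activation in 11 of 25 (13, 0.0179). Under total-sum scaling 10 G2/M genes were lower (median -0.39 to -0.27), 5 of ribosome biogenesis (-0.26 to -0.14), 4 of purine synthesis (-0.2 to -0.08) and 6 NRF2 targets (-0.32 to -0.2). The calls of ribosomal proteins (11 of 59 lower, adjusted p = 0.284 with an estimated correlation; median -0.19, and 0 under quantile normalization), glycolysis (8 of 26 lower, 0.138), the respiratory chain (10 of 33 lower, 0.0822) and mitochondrial mRNAs (0 of 13; 0.635) were lost. Of 1991 genes 33.8% were higher, but total-sum scaling gave 69.95% and quantile normalization 51.75%. Total-sum scaling moved the median of all genes from 0.02 to 0.134. With position in the fit 720 genes passed, without replicate 3 of day 3 at 100% 588, and without replicate 1 of day 6 at 100% 1298. FN1 measured 1616 ± 1265 on day 3 and 2463 ± 617.5 on day 6, and followed the library number in steps of 8, as described below.

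The effect of restriction was compared between days without shared libraries. At 25% histidine 1223 genes rose on both days, of 2256 and 2521, where independent lists would share 247.3, and 1066 fell on both, of 2234 and 2124 (206.4 for independent lists). At 12.5% the numbers were 1717 of 3257 and 2482 (351.6), and 1542 of 2761 and 2554 (306.7). The log2 changes of the 2 days had a Pearson correlation of 0.2338 and a Spearman correlation of 0.2895 across genes at 25%, and 0.3653 and 0.4129 at 12.5%. Genes are not independent replicates. TXNIP, SNHG12, IMPDH2, RAG2 and QARS1 moved the same way on both days, for example QARS1 by -1.59 and -1.58 at 25%. The effect itself differed between days in 1086 genes at 25%, 57.46% of them with a higher log2 change on day 6 (32.89% under total-sum scaling, 42.78% under quantile normalization). At 12.5% it differed in 836 genes, with a higher log2 change on day 6 in 294 and a lower one in 542. With position in the fit the counts were 407 and 549, and leaving out 1 library lowered them to as few as 654 and 379. At 50% it differed in 1 gene, KLHDC7B, with 906 at an unadjusted p under 0.05, and in 0 with position in the fit.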

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

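The test of handling or density below was chosen only after the result was seen, and the test of library position was set before. What singled out the results of this part is a test of the difference between days in the effect of restriction, with limma. A positive difference means a higher log2 change on day 6 than on day 3.

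The heat shock gene HSPA1B had high levels on day 3 at 100% and 50% histidine and low levels elsewhere. Not all heat shock genes did so, since HSPA8, HSPA4 and DNAJA1 were higher at 0% than at 100% on day 3. HSPA1B measured 19940 ± 1811 (n = 2) and 23930 ± 4208 (n = 3) in those groups, against 267.1 ± 123.7 at 25% on day 3 and 720.8 ± 350.4 at 100% on day 6. The difference between days was 5.1 at 25% and 5.21 at 12.5% for HSPA1B, 4.76 and 5.6 for HSPA6, and 3.79 at 12.5% for HSPA1A. A position effect with a step of 8 is argued against for HSPA1B. Between 50% and 25% on day 3 HSPA1B changed by -6.55 (SE 0.495) with position in the fit and by -6.56 (SE 0.314) without it. The 5 libraries with high HSPA1B have the numbers 1 to 5 in the labels. The fit therefore cannot tell another effect of library order from the groups. Handling or density of the cells behind these 5 libraries may also raise heat shock transcripts, and cannot be told apart from histidine and day, since the list's median between the days at 100% (-1.16) is what either would give and no label records handling.

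The effect of 25% histidine differed between days in 1086 genes and 16 lists, 9 of them also with an estimated correlation (adjusted p of at most 0.0329, and at least 0.0973 for the other 7). The median differences of those 9 were 1.42 for cytosolic heat shock proteins (14 of 15 higher), 1.37 for T-cell activation, 0.98 for replication-dependent histones (0 of 18 called), 0.7 for cholesterol synthesis (13 of 24), 0.7 for G2/M and mitosis (21 of 25), 0.26 for NRF2 and redox, -0.18 for serine, proline and one-carbon synthesis, -0.22 for ATF4 and CHOP targets (8 of 24 lower) and -0.97 for endoplasmic reticulum chaperones (17 of 19 lower). Between the days at 100%, heat shock, T-cell activation, cholesterol, G2/M and NRF2 genes were lower, and ATF4 targets and endoplasmic reticulum chaperones higher. The differences of these lists have the opposite sign. The days were not compared at 25% itself, so a changed response to restriction cannot be told from the shift at 100%. IER5L differed by 3.32. RIGI differed by -5.13, and its 2 day 3 libraries at 100% measured 20.14 and 0. Without replicate 3 of day 3 at 100% the count of genes was 654.

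The effect of 12.5% histidine differed between days in 836 genes and 17 lists, 7 of them also with an estimated correlation (adjusted p of at most 0.0393, and at least 0.0775 for the other 10). The median differences of those 7 were 1.82 for T-cell activation (11 of 25 higher), 0.95 for cytosolic heat shock proteins (12 of 15), 0.68 for cholesterol synthesis (14 of 24), 0.3 for NRF2 and redox, -0.25 for serine, proline and one-carbon synthesis, -0.27 for ATF4 and CHOP targets (9 of 24 lower) and -1.11 for endoplasmic reticulum chaperones (17 of 19 lower). The T-cell activation, heat shock, cholesterol, NRF2, ATF4 and chaperone differences were again opposite in sign to the shifts between days at 100%. The same limit holds for them. RIGI differed by -5.01. The count of genes was 392 without replicate 1 of day 3 at 100%, 379 without replicate 2 and 442 without replicate 1 of day 6 at 12.5%.

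The effect of 50% histidine differed between days in 1 gene, KLHDC7B (2.01), with 906 genes at an unadjusted p under 0.05, and in 10 lists, 1 of them with an estimated correlation (adjusted p = 0.00761, and at least 0.0654 for the other 9): cholesterol synthesis, with a median of -0.28 (0 of 24 called over all genes and 7 adjusted over the list alone).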

How the results depend on the processing

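Of the fits in this part only those with a position term and without 3 libraries were chosen after seeing the data. Planned tests on whole reads with edgeR and DESeq2 were not run, because whole reads could not be recovered from the normalized values, so the counting error behind low values is unknown. For 879 values of named genes, 13977 alternative values were computed. Direction was compared only for values that passed in the main fit. Of the alternatives, 13355 stayed on the same side of the threshold, 550 kept the direction and no longer passed, 70 newly passed, and 2 turned. The 2 were CALR in day 3, 25% against 100% (0.01 under quantile normalization, adjusted p = 0.975) and FTH1 in day 3, 25% against 50% (0.15 under quantile normalization, adjusted p = 0.0817). Their cause was not tested. Where fewer libraries were fitted, the loss of samples is part of the change, and elsewhere the cause was not tested. Where a group kept 1 library, it was assumed to vary like the other groups.

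Counts of changed genes that moved by over 1.5 times were as follows. With a pseudocount of 10 the difference between days at 50% gave 0. With quantile normalization day 3, 12.5% against 25% gave 1232, and day 3, 50% gave 4 lists. With only the compared groups in the fit day 3, 50% gave 5, day 6, 50% gave 4, the difference at 50% gave 0 and day 6, 12.5% against 25% gave 12. With array weights day 6, 50% gave 5 and day 6, 12.5% against 25% gave 328. With the position term (7 terms, 9 residual degrees of freedom) the counts against 100% were 2350 at 25% and 4725 at 0% on day 3, and 0 at 50% and 3012 at 25% on day 6. They were 720 for day 6 against day 3, 0, 407 and 549 for the differences at 50%, 25% and 12.5%, 3183, 238 and 2723 for the steps down on day 3, and 2432 and 32 for those on day 6. Without the 3 day 6 libraries (100% replicate 3, 50% replicate 3 and 25% replicate 2), day 6, 50% gave 0, the difference at 50% gave 0 and day 6, 12.5% against 25% gave 100. Total-sum scaling, no filter, the strict filter, a pseudocount of 0.5 and the replicate block moved no total of genes or lists of a comparison by over 1.5 times. Total-sum scaling did move the balance: genes higher on day 6 than on day 3 at 100% went from 673 to 1383, and those higher at 12.5% than at 25% on day 3 from 1243 to 583. Genes lower in the difference at 25% went from 462 to 851.

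Shifted lists were fewer with an estimated correlation: against 100%, 0 at 50%, 5 at 25%, 8 at 12.5% and 7 at 0% on day 3, and 3, 7 and 7 at 50%, 25% and 12.5% on day 6. They were 1, 9 and 7 for the differences, 5, 2 and 4 for the steps on day 3 and 6 and 3 for those on day 6. With fry the counts that moved were 0 for day 3, 50%, 3 for day 6, 50%, 1 for the difference at 50%, 14 for day 3, 0% against 12.5%, 19 for day 6, 25% against 50% and 4 for day 6, 12.5% against 25%.

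Leaving out each library in turn, against 100% on day 3, gave 0 to 5 genes and 1 to 12 lists at 50%, 2954 to 3934 and 11 to 14 at 25%, 4431 to 5486 and 14 to 16 at 12.5%, and 5422 to 6593 and 11 to 14 at 0%. On day 6 it gave 0 to 17 and 8 to 11 at 50%, 3670 to 4239 and 12 to 16 at 25%, and 3175 to 4414 and 15 to 17 at 12.5%. Day 6 against day 3 gave 588 to 1874 genes and 14 to 15 lists. The differences gave 0 to 5 and 7 to 11 at 50% (5 without replicate 1 of day 6 at 100%), 654 to 1057 and 14 to 17 at 25%, and 379 to 756 and 15 to 18 at 12.5%. The steps on day 3 gave 4527 to 4778 and 13 to 14 (25% against 50%), 1135 to 1451 and 11 to 15 (12.5% against 25%), and 4065 to 4228 and 8 to 9 (0% against 12.5%). Those on day 6 gave 3814 to 4283 and 12 to 17 (25% against 50%), and 74 to 322 and 8 to 12 (12.5% against 25%).

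The replicate numbers did not pair the libraries: over 92 pairs of the same number the correlation of deviations ran from -0.106 to 0.192 (median 0.0015, 1 above 0.1), and 7 of 25 libraries matched best with their own number. With the replicate number as a block no count of genes or lists moved by over 1.5 times: 4382, 5834 and 7002 genes passed at 25%, 12.5% and 0% on day 3, and 4594 and 4837 at 25% and 12.5% on day 6.

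Comparisons of 3 against 3 libraries have 10 splits, too few for a share under 0.05. Of the 10, 4 gave as many genes as day 6, 50% (1 gene, highest other 2). For genes in day 6, 25% against 100% (4645, highest other 0), day 3, 25% against 50% (5475, 0), 12.5% against 25% (1889, 1), 0% against 12.5% (4818, 4) and day 6, 25% against 50% (4807, 0), 1 split did, the real one. For lists at the preset correlation, in the order of these 6 comparisons, 1 (11, highest other 10), 4 (13, 15), 2 (14, 15), 1 (13, 10), 2 (9, 9) and 4 (12, 17) did. With an estimated correlation the real split gave 3, 7, 5, 2, 4 and 6 lists and the highest other 1, 0, 0, 1, 0 and 0.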

Other observations

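The gene families here, the tests of another organism, of human heart muscle and of histidine against the heart transcripts, and the test of HBA2 within groups were chosen only after the result was seen. The tests of held-out heart genes, of library numbers in steps of 8 and of the histidine content of proteins were set before their results. The step of 8 had itself been seen first in these libraries, so its comparison with other steps is no independent test. Of 16 families 15 kept at least 5 members once genes already named or in a fixed list were left out, and were tested in each of 5 comparisons against 100%. With an estimated correlation 3, 3 and 4 of the 15 passed at 25%, 12.5% and 0% on day 3, and 4 and 3 at 25% and 12.5% on day 6. Since the families were chosen with values in view, these p-values describe them and are no independent test. Fatty acid synthesis and desaturation fell beside the sterol genes: 10 of 10 members at 25%, 12.5% and 0% on day 3 (medians -0.96, -1.17 and -1.12, adjusted p = 0.00137, 0.00238 and 0.00499 with an estimated correlation), and 7 and 8 at 25% and 12.5% on day 6 (-0.45 and -0.76, 0.0191 and 0.0188). The desaturase SCD changed by -2.66 (SE 0.089) and FASN by -2 (SE 0.103) at 12.5% on day 3.

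GIMAP genes, a cluster of GTPases of lymphocytes, fell in 5, 6 and 6 of 7 at 25%, 12.5% and 0% on day 3 (adjusted p = 0.00685, 0.0064 and 0.0144 with an estimated correlation) and in 5 and 6 at 25% and 12.5% on day 6 (0.0191 and 0.021). GIMAP4 changed by -3.72 (SE 0.34) at 0%. Histone variants made outside S phase (H1, H2A.Z and H3.3 types) rose in 7 of 8 at 12.5% on day 3 (0.0336) and in 8 of 8 at 25% and 12.5% on day 6 (0.0276 and 0.0244), and the family did not pass at 25% or 0% on day 3 (0.262 and 0.546). At 0% vacuolar ATPase subunits had 9 of 18 higher and 1 lower, and kinesins 15 of 32 lower and 4 higher (both 0.0493). Zinc finger genes had 68 of 440 lower and 22 higher at 25% on day 3 (0.00952), and translation elongation factors 6 of 6 lower at 25% on day 6 (0.0446). The kinesins had an adjusted p of 0.056 at 25% on day 6, with 12 higher and 1 lower.

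Heart muscle transcripts stood apart in the library of replicate 2 at 25% histidine on day 6, with MYH7 at 18210, MYH6 at 12190, ACTC1 at 7458 and DES at 748.5. Of 21 heart genes held out from the search, 42.86% stood apart, which left heart RNA as such undecided. Histidine at 25% is argued against, since the other 2 libraries of the group held at most 0.2194% of that MYH7. Human heart muscle was left undecided. TNNT2, TNNI3, MB, PLN and FABP3, abundant there and picked after values had been seen, were at most 0.137% of MYH7. Other heart muscle genes stood apart in the library, among them MYL3 at 12350, TNNC1 at 4729 and MYBPC3 at 2331. Reads of another organism remain a candidate source: of 232 genes standing apart in this library 185 had an annotated type, and 58 of these (31.35%) were processed pseudogenes, against 386 of the 16827 tested genes with an annotated type (2.294%; two-sided Fisher's exact p = 4.87e-50), as reads matched across species would give. No biological explanation beyond the histidine level was tested.

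Some haemoglobin, matrix and fat cell transcripts followed the number of the library in the labels in steps of 8. With a modulus of 8, 53 genes had a position effect, among them HBA2, FN1, MMP1, THBS1, ADIPOQ and FABP4, against 0 at 5, 0 at 7 and 2 at 10, while 6 and 9 could not be fitted. The step was first seen in haemoglobin and collagen genes, and with the group in the limma fit over all genes the adjusted p was 4.34e-09 for HBA2 and 7.14e-09 for FN1, but 0.161 for COL1A1. The haemoglobin gene HBB and the collagen gene COL3A1 were not among the 53 either. Without the group, the step took 83.16% of the variance of log2 values for HBB and 71.77% for COL3A1. By permutation of the libraries the adjusted p was 4e-04 and 0.00086, in kinds of genes where the step was first seen. HBB was at 2747 in the library with MYH7, number 22, against 103.2 and 140.2 in numbers 6 and 14. Histidine and day are argued against, since HBA2 differed by up to 40.69-fold between replicates of 1 group (day 6, 50%). What is left may be carry-over between neighbouring samples or wells at a step of 8, which no label describes.

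The hypothesis that mRNAs whose proteins hold more histidine fall more was tested without histidine on day 3. Over 14515 genes the log2 change at 0% and the histidine share of the protein had a Spearman rho of -0.04 across genes, which are not independent replicates, -0.018 after the trend with expression was removed and -0.05 without zinc finger genes. Histidine had the lowest rho of the 20 amino acids before that trend was removed, with cysteine next at -0.025, but after it asparagine (-0.032), aspartate (-0.03) and lysine (-0.024) lay lower. The size set beforehand, a rho below -0.1, was not reached.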
